A study of Rattus norvegicus with 24 samples.

How the data were processed

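Total RNA from the left dorsal striatum of rats, prepared with Trizol and labelled with Cy3, was hybridised to 24 Agilent one-colour arrays, 8 per group and 3 slides of 8. Per the file headers, the processed signal of each spot is an intensity that Feature Extraction (version 10.7 in the submitters' processing notes) had background-subtracted and detrended within the array, with no normalization between arrays. Per the file headers, the other columns used were the mean spot and median local background intensities and flags of 0 or 1 for spots well above background, saturated or uneven. The authors' value table holds log2 values that rank as the processed signals of each array do and share their minimum of 2.68 and maximum of 18.1 across arrays, as quantile normalization leaves them. The method behind that table is not stated. Probe coordinates are those of the file headers' rat build rn4 and were not checked against a genome.

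Values were log2 processed signals minus the array's 75th percentile of non-control probes. Control spots and spots marked uneven or as population outliers were left out, which left 63 missing values. Of 45598 probes, 26259 were kept, those well above background on at least a 0.5 share of the arrays of at least 1 group. A gene was represented by its probe with the highest mean, which gave 20388 genes, 13861 of them with a symbol, and 4510 with more than 1 kept probe. Arrays of a shared title letter were averaged, since the series design states 6 per group. Groups were compared with limma 3.58.1 (lmFit, contrasts and eBayes, all 3 groups sharing 1 estimate of the spread) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and an F test over the 3 groups. In the comparisons, differences are the first group named minus the second. Lists of genes, 25 of function and 16 of cell type or tissue markers, were tested by limma's camera with a preset correlation of 0.01, adjusted over the 41 lists and 3 comparisons. The smallest list tested held 5 measured genes. Camera compares the list with the other genes, and with an estimated correlation it also allows for genes of a list that vary together. Fry tests whether a list's genes move one way on balance, or, in its mixed form, in either direction, and compares the list with no other genes (mixed form, smallest adjusted p = 0.987). The list level of a unit is the mean of its members' values, compared by exact two-sided permutation. With 6 units per group, a list standing alone could not pass this test after adjustment over 41 lists and 3 comparisons. Relations between list levels over the 18 units were given as Pearson's r and Spearman's rho with two-sided permutation tests of 100000 permutations, over 6 relations chosen after list levels were seen.

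The genes named follow a rule, apart from list members given as examples, which were chosen after their values were seen. Those of the rule are, in each comparison, the 10 with the smallest p in each direction among genes with a symbol, of which the text may give the first 5, members of a list past the threshold over all genes or over the list alone, at most 4 per list, and 20 genes given whatever their values, of which 18 were measured. The lists, the comparisons and most alternatives were fixed with them. The alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' values, other filters on dim probes, each probe tested alone, 24 arrays as independent samples, the letter as a random block, 1 array per letter, slide as a block, each slide alone, title series as a block, only the compared groups, robust and trended moderation, array weights, outlier spots kept, other list tests and each unit left out in turn. Another 5 alternatives were chosen after seeing the data: choroid plexus and cortex list levels as covariates with 18 units or with 24 arrays, saline replicate 4 left out as an array, that array left out with saline replicate 5 and chronic replicate 8, and the exact permutation of list levels. Gene counts were tested on simulated data in which 1.5-fold changes were recovered in 52%, 58% and 64% and 2-fold changes in 88%, 78% and 85% of changed genes in the 3 comparisons, with 9, 14 and 25 unchanged genes called beside 200, 200 and 400 changed ones. In these simulated data genes varied independently and changes of up to 4-fold were planted. The ribosomal list was also lowered as a whole in the chronic group. In the comparisons with that group its genes were counted neither as changed nor as unchanged. Recovery on the real arrays, whose genes vary together and of which fewer may change, may differ and was not measured. Other splits of the samples, 100 per result, were drawn with a fixed seed. R 4.3.3, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.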

Results

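The arrays measured RNA in the left dorsal striatum, a forebrain region that receives dense dopamine input, of male Long Evans rats given MDPV (methylenedioxypyrovalerone), a synthetic cathinone that blocks the uptake of dopamine and noradrenaline. Rats aged 80 to 90 days had 1 injection on each of 5 days. In the saline group none of these held the drug, in the acute group the last one did, and in the chronic group all 5 did, at 1 mg/kg. The brains were taken 24 h after the last injection. There were 24 arrays, 8 per group, on 3 slides. Slides 1 and 2 each held 3 saline, 2 acute and 3 chronic arrays, and slide 3 held 2 saline, 4 acute and 2 chronic arrays. The series design states 6 per group. In each group 4 arrays carry titles of their own, and 4 carry a letter with the digit 0 or 1, so the arrays of a shared letter were averaged, which gave 18 units, 6 per group. Arrays of a shared letter were not more alike than other arrays of a group on different slides: the median correlation of their deviations across genes was -0.262, against -0.0985 for the other pairs (exact one-sided p = 0.852 over 27 pairings). As a random block the letter had a consensus correlation of -0.368. The median SE was then 0.119, against 0.137 with independent arrays, so gene counts under that block rest on smaller SEs. The arrays of a letter are therefore not shown to come from 1 rat. The main fit and the SDs over units give a single array and a mean of arrays sharing a letter the same weight. For lists that passed, gene counts and the correlation of effects, values with 24 independent arrays are given beside the main ones. The differences of single genes are not given with 24 independent arrays. Between 50.7% and 71.3% of the 58717 non-control spots of an array were well above background, none was saturated, and the median signal was 6.45 to 10.4 times the background. After filtering, 20388 genes were tested, with a median SE of 0.14 for a log2 difference between groups. The number of arrays limits this precision, and the p-values of single genes rest on the spread between samples. Those of camera with a preset correlation compare a list with the other genes. They allow little for genes of a list that vary together between samples.

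Transcripts of striatal projection neurons were abundant on every array. Values below are log2 signals relative to the array's 75th percentile. Ppp1r1b, the dopamine-regulated phosphatase inhibitor of these neurons, had means of 4.44 ± 0.72 in saline, 4.56 ± 0.25 in acute and 4.70 ± 0.28 in chronic rats (SD, n = 6 units each). Penk, the enkephalin precursor of the indirect pathway, had 3.78 ± 0.55, 3.99 ± 0.19 and 4.02 ± 0.15. Some transcripts of neighbouring tissue varied far more between arrays. Ttr, the transthyretin gene that choroid plexus expresses at very high levels, ran from -5.62 on chronic replicate 3 to 6.28 on saline replicate 3, a 3815-fold range, and differed by 1.48 to 8.10 within the 6 pairs of a shared letter. Slc17a7, the vesicular glutamate transporter of cortical neurons, ran from -8.50 on chronic replicate 8 to -2.53 on chronic replicate 2. It was well above background on 21 of the 24 arrays, so its lowest values may lie near background. Saline replicate 4 had the highest Avp (2.60), Oxt (1.99) and Pmch (0.86), which encode hypothalamic peptides, and the lowest Drd1 (1.89), Drd2 (1.90), Ppp1r1b (3.10), Penk (2.88), Tac1 (2.91) and Adora2a (0.33). Its mean level of the pan-striatal projection neuron list was 0.46, and the other 23 arrays had 0.95 or more. The first principal component held 24.5% of the variance over 24 arrays. It followed the choroid plexus list (r = -0.644) and the cortex list (r = 0.647), and 9.06% of it lay between groups and 10.2% between slides. Over the 18 units, the thalamus, septum and pallidum list fell as the pan-striatal list rose (r = -0.791, permutation p = 0.00198, adjusted p = 0.00594 over 6 relations), with r = -0.846, -0.635 and -0.650 within slides 1, 2 and 3. This relation, with the 3 groups pooled, was 1 of 6 chosen after list levels were seen, which the adjustment does not cover. Its Spearman's rho was -0.360 (permutation p = 0.143, adjusted p = 0.327), and without the 2 units farthest from the median r was -0.328, so the pooled relation rests on those units, although slides 1 and 3 do not hold saline replicate 4.

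**Figure D1:**
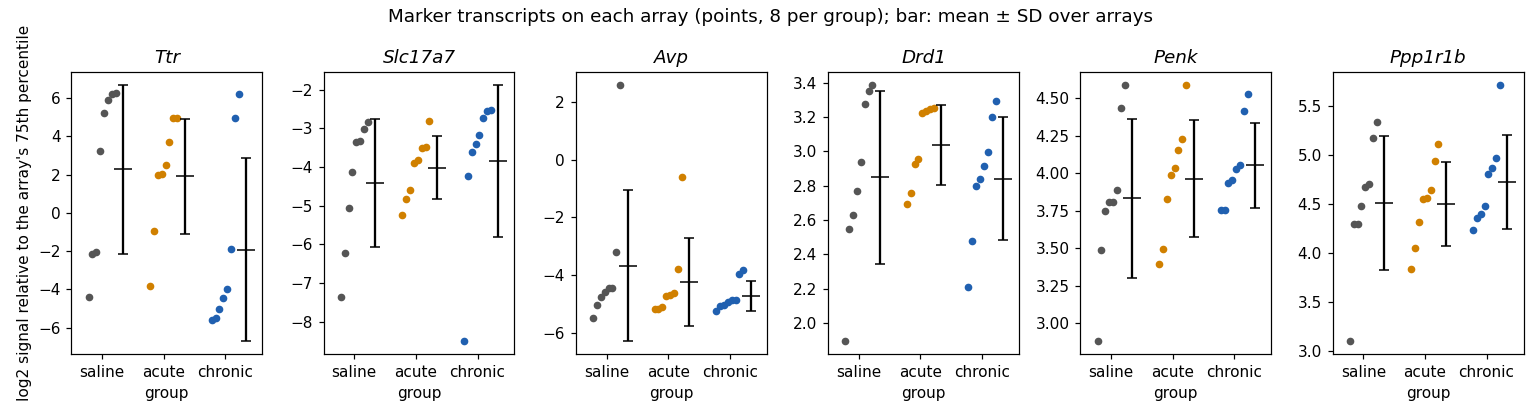
Log2 signal relative to the array's 75th percentile (vertical axis) of 6 marker transcripts on each array (points, 8 per group), with the mean and SD over arrays (bars). Ttr spans -5.62 to 6.28, and the saline array with the highest Avp (2.60) has the lowest Drd1, Penk and Ppp1r1b.

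Acute against saline asks what a single dose left in the striatum a day later. Transcripts of dopamine signalling in projection neurons were slightly higher in acute rats. Of 23 measured members of the dopamine receptor and striatal cAMP list, 21 were higher, with a mean shift of 0.17 log2 (list level 1.54 ± 0.13 against 1.37 ± 0.41, SD, n = 6 per group). Its members include Drd1, the dopamine receptor of direct-pathway neurons, at 0.29 (SE 0.20), Drd2, that of indirect-pathway neurons, at 0.25 (SE 0.23), Adora2a, the adenosine receptor of the latter, at 0.28 (SE 0.24), and the phosphodiesterase Pde7b at 0.48 (SE 0.30). None of these genes passed alone, and the list members named as examples here and further on were chosen after their values were seen. The lists of pan-striatal neurons (16 of 17 higher, 0.17), direct-pathway neurons (7 of 9, 0.17), indirect-pathway neurons (7 of 8, 0.22), voltage-gated and inward rectifier channels (23 of 34, 0.08) and ERK feedback and delayed activity genes (15 of 19, 0.10) were higher as well. In this order the 6 lists had adjusted p = 0.000373, 0.00431, 0.0276, 0.0206, 0.00533 and 0.0304 by camera with a preset correlation. With an estimated correlation none passed: adjusted p = 0.866 with an estimated correlation for the pan-striatal list and adjusted p = 0.841 with an estimated correlation for the other 5. Of the pan-striatal genes, 5 are also in the dopamine list. All 6 calls ended without saline replicate 4, the array lowest in striatal transcripts, where the shifts were 0.02 (adjusted p = 0.745), 0.01 (adjusted p = 0.913), 0.04 (adjusted p = 0.706), 0.06 (adjusted p = 0.706), 0.02 (adjusted p = 0.464) and 0.01 (adjusted p = 0.745). Without saline replicate 3, the pan-striatal, direct-pathway and indirect-pathway lists had adjusted p = 0.0869, 0.217 and 0.0980. Calls also ended without acute replicate 3 (direct pathway, 0.0595), without acute replicate 5 (direct pathway, 0.0977, indirect pathway, 0.112, and ERK, 0.202), and for the ERK list without saline replicates 2 and 5 (0.0829), acute replicate 2 (0.0541) or acute replicates 4 and 6 (0.0623). The ERK shift did not fall without acute replicate 2 (0.11) or acute replicates 4 and 6 (0.11). It fell to 0.09 without saline replicates 2 and 5 and to 0.06 without acute replicate 5. With slide as a block the shifts were 0.12 (adjusted p = 0.0391), 0.10 (adjusted p = 0.132), 0.13 (adjusted p = 0.119), 0.17 (adjusted p = 0.137), 0.06 (adjusted p = 0.0778) and 0.05 (adjusted p = 0.485), so the dopamine call alone held. Without saline replicates 4 and 5 and chronic replicate 8, left out after seeing the data, the shifts were -0.04 (adjusted p = 0.912), -0.05 (adjusted p = 0.873), 0.02 (adjusted p = 0.934), 0.00 (adjusted p = 0.934), 0.00 (adjusted p = 0.799) and -0.02 (adjusted p = 0.934), so none passed and 5 were below 0. With 24 independent arrays they were 0.09 (adjusted p = 0.0287), 0.09 (adjusted p = 0.142), 0.11 (adjusted p = 0.158), 0.14 (adjusted p = 0.158), 0.07 (adjusted p = 0.00618) and 0.09 (adjusted p = 0.0423), and the pan-striatal, direct-pathway and indirect-pathway calls ended. All 6 calls ended with the choroid plexus and cortex levels as covariates, an alternative chosen after seeing the data, at 0.07 (adjusted p = 0.118), 0.07 (adjusted p = 0.324), 0.07 (adjusted p = 0.401), 0.12 (adjusted p = 0.371), 0.04 (adjusted p = 0.164) and 0.07 (adjusted p = 0.0913). Within slides 1, 2 and 3 they were 0.01, 0.38 and -0.08 for the dopamine list, -0.02, 0.42 and -0.08 for pan-striatal, 0.01, 0.42 and -0.03 for direct-pathway, 0.11, 0.46 and -0.08 for indirect-pathway, 0.05, 0.08 and 0.04 for channel and -0.02, 0.12 and 0.03 for ERK genes.

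Markers of choroid plexus, thalamus, blood and oligodendrocytes and interferon response genes were lower in acute than in saline rats, while cortex markers did not pass (9 of 11 higher, 0.20, adjusted p = 0.264). All 9 measured choroid plexus and ependyma markers were lower, by a mean of -1.04 log2 (list level -3.39 ± 0.67 against -2.35 ± 1.61, SD, n = 6 per group), among them the potassium channel Kcnj13 -1.90 (SE 0.88) and the folate receptor Folr1 -1.50 (SE 0.86). All 10 markers of thalamus, septum and pallidum were lower (-0.35), with Slc17a6, the vesicular glutamate transporter of thalamic neurons, at -0.66 (SE 0.41). All 10 blood cell transcripts were lower (-0.32), with the haemoglobin gene Hbb at -0.29 (SE 0.22) and the antigen-presentation chain Cd74 at -0.63 (SE 0.41). Of the interferon response genes 15 of 18 were lower (-0.19), with Isg15 at -0.54 (SE 0.31) and Irf7 at -0.48 (SE 0.35), and of the oligodendrocyte markers 13 of 14 (-0.12), with the myelin enzyme Cnp at -0.28 (SE 0.21). In this order the adjusted p values were 1.03e-05, 0.000411, 0.000411, 0.00270 and 0.0292. With an estimated correlation none of the 5 passed: adjusted p = 0.877 with an estimated correlation for oligodendrocytes and adjusted p = 0.841 with an estimated correlation for the others. Without saline replicate 4 the shifts were -0.74 (adjusted p = 0.00204), -0.11 (adjusted p = 0.401), -0.31 (adjusted p = 0.00204), -0.11 (adjusted p = 0.454) and -0.02 (adjusted p = 0.913). The blood list had -0.18 (adjusted p = 0.0804) without acute replicate 3, and the oligodendrocyte list -0.07 (adjusted p = 0.324) without that array, -0.10 (adjusted p = 0.106) without acute replicate 2 and -0.09 (adjusted p = 0.0657) without acute replicate 7. All 5 calls held with slide as a block, at -1.26 (adjusted p = 1.08e-06), -0.22 (adjusted p = 0.0210), -0.37 (adjusted p = 3.89e-06), -0.15 (adjusted p = 0.0235) and -0.18 (adjusted p = 0.000151). With 24 independent arrays the shifts were -0.78 (adjusted p = 0.00311), -0.32 (adjusted p = 0.000813), -0.36 (adjusted p = 9.19e-06), -0.15 (adjusted p = 0.0282) and -0.07 (adjusted p = 0.224), and the oligodendrocyte call ended. Without those 3 arrays (saline replicates 4 and 5 and chronic replicate 8) all 5 calls ended, at -0.41 (adjusted p = 0.208), 0.01 (adjusted p = 0.912), -0.22 (adjusted p = 0.157), -0.03 (adjusted p = 0.952) and 0.02 (adjusted p = 0.909). The covariates left thalamus at -0.28 (adjusted p = 0.0474), blood at -0.23 (adjusted p = 0.0913), interferon at -0.18 (adjusted p = 0.0781) and oligodendrocytes at 0.01 (adjusted p = 0.665). With the covariates over 24 arrays the thalamus call ended, at -0.24 (adjusted p = 0.0764), and the blood call held, at -0.26 (adjusted p = 0.0308). Within slides 1, 2 and 3 the shifts were -1.08, -2.14 and 0.60 for choroid plexus, 0.05, -0.81 and -0.02 for thalamus, -0.02, -0.997 and -0.18 for blood, 0.00, -0.42 and -0.04 for interferon and 0.14, -0.46 and 0.02 for oligodendrocytes. Of the 41 lists, 11 passed with the preset correlation, and none by fry or by an exact permutation of the list means (smallest adjusted p = 0.909 and 0.877). The other 30 lists had adjusted p of 0.0854 or more. Without saline replicate 4 the count was 3: the choroid plexus and blood lists, and a list that was not among the 11.

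No single gene passed limma's threshold of an adjusted p of 0.05 between acute and saline rats (smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 324 genes, where 1019 would be expected by chance. The count was 289 with 24 arrays as independent samples, 359 with slide as a block, 678 with the shared letter as a random block and 746 with array weights. It was 780 with normexp background correction and quantile normalization, and 591 without acute replicate 2. Among the genes with the smallest p, Cmtm8, a transmembrane protein of the chemokine-like factor family (chromosome 8, 119209277 to 119209336 in the rat build rn4), had means of -4.50 ± 0.18 in acute and -4.07 ± 0.16 in saline rats (SD, n = 6 per group), a difference of -0.43 (SE 0.11), and -0.73, -0.32 and -0.30 within slides 1, 2 and 3. Also lower were the centromere protein Cenpn -0.46 (SE 0.12), the matrix metalloproteinase Mmp2 -0.51 (SE 0.14), whose other probe gave -0.07, the prostaglandin E receptor Ptger3 -0.71 (SE 0.20) and the amidase Nit2 -0.62 (SE 0.18), with within-slide values of -0.13, -0.56 and -0.65 for Cenpn, -0.29, -1.02 and -0.17 for Mmp2, -1.66, -0.48 and -0.18 for Ptger3 and -0.32, -1.02 and -0.46 for Nit2. The higher genes were led by Edn1, which encodes the vasoconstrictor endothelin (chromosome 17, 28304023 to 28304082), with 0.56 (SE 0.16) and within-slide values of 0.71, 0.85 and 0.04. They included the matricellular protein Ctgf 0.56 (SE 0.18), the neuronal splicing factor Rbfox3 0.28 (SE 0.09), whose other probe gave 0.07, the zinc finger gene Zfp324 0.58 (SE 0.19), well above background on 4 of 8 acute and 1 of 8 saline arrays, and the immune receptor adaptor Hcst 0.73 (SE 0.24). Their within-slide values were 0.23, 0.78 and 0.24 for Ctgf, 0.08, 0.41 and 0.26 for Rbfox3, 0.83, 0.20 and 0.98 for Zfp324 and 0.39, 0.87 and 0.60 for Hcst. The 10 differences ran from -0.72 for Ptger3 to 0.73 for Zfp324 with slide as a block. Each of these 10 genes had an adjusted p of 1.00.

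Genes chosen before the data were examined did not differ detectably between acute and saline rats. The immediate early genes, which neurons switch on within minutes of activity, were Fos -0.16 (SE 0.28), Fosb 0.09 (SE 0.23), Junb -0.16 (SE 0.25), Egr1 -0.07 (SE 0.25), Arc 0.17 (SE 0.30) and Nr4a1 0.20 (SE 0.25). Receptors, peptides and signalling genes of projection neurons were Drd1 0.29 (SE 0.20), Drd2 0.25 (SE 0.23), Ppp1r1b 0.12 (SE 0.25), Penk 0.21 (SE 0.19), Pdyn 0.33 (SE 0.20), Tac1 0.18 (SE 0.20) and Cartpt 0.26 (SE 0.66). The growth factor Bdnf, the clock genes Per1 and Per2, the glucocorticoid target Fkbp5 and the dopamine synthesis enzyme Th were Bdnf 0.04 (SE 0.43), Per1 0.06 (SE 0.15), Per2 0.05 (SE 0.11), Fkbp5 0.18 (SE 0.14) and Th -0.27 (SE 0.23). The 95% intervals leave room for changes: that of Fos ran from -0.76 to 0.44, that of Pdyn from -0.10 to 0.76 and that of Drd1 from -0.13 to 0.71. Another probe of Per1 gave -0.04. Pdyn had -0.30, 0.90 and 0.30, Drd1 -0.12, 0.58 and 0.19 and Fos -0.52, 0.35 and -0.38 within slides 1, 2 and 3, and each of the 18 genes kept its sign with slide as a block. Signs did not hold under every alternative: over all of them Ppp1r1b ran from -0.59 to 0.46 and Fosb from -0.71 to 0.60. Npas4 and the dopamine transporter gene Slc6a3 were well above background on at most 8 and 4 of the 24 arrays and were not tested.

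**Figure D2:**
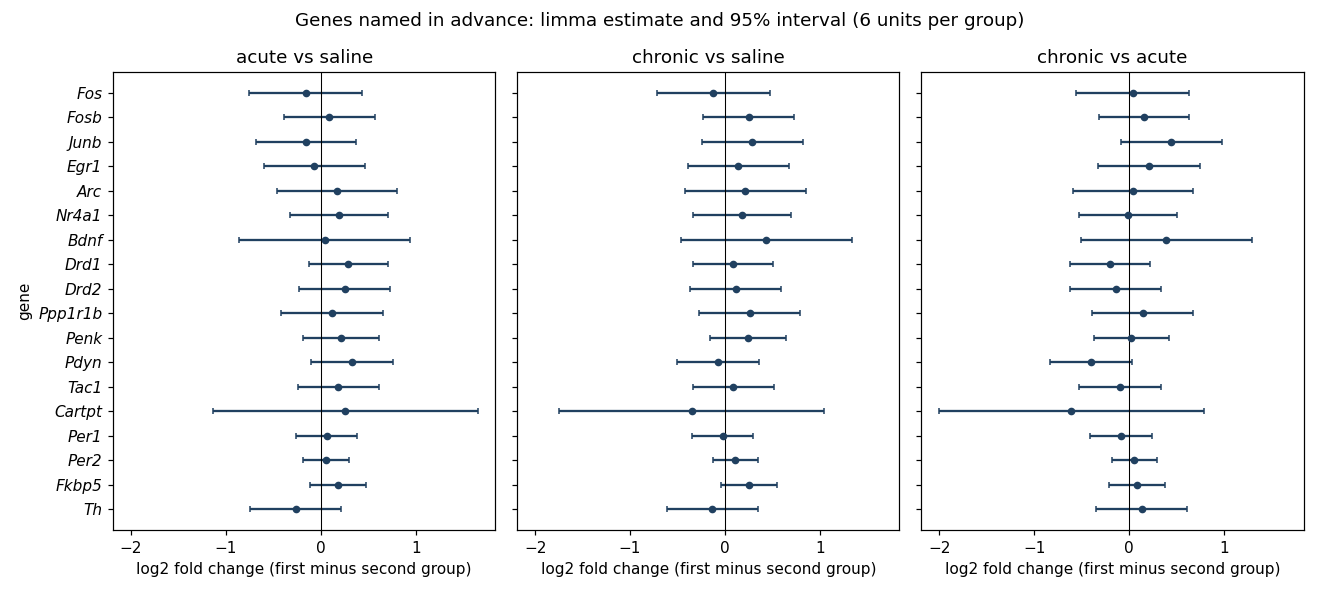
Log2 fold change (horizontal axis, limma estimate with 95% interval, 6 units per group) of the 18 measured genes named in advance in the 3 comparisons. Every interval includes 0, and the interval of Cartpt is the widest, from -2.01 to 0.79 for chronic against acute.

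Chronic against saline asks what 5 daily doses left. Ribosomal protein transcripts were slightly lower in chronic rats: 51 of 53 were lower, by a mean of -0.09 log2 (list level 4.04 ± 0.06 against 4.13 ± 0.11, SD, n = 6 per group), with Rpl19 at -0.21 (SE 0.09). Transcripts of presynaptic vesicle release were higher (21 of 23, 0.16), with the vesicle proteins Sv2b 0.52 (SE 0.28) and Syn1 0.29 (SE 0.26) and the membrane fusion protein Snap25 0.26 (SE 0.16). So were those of the postsynaptic density (23 of 31, 0.09), actin and spine regulators (20 of 23, 0.12), with the activity-regulated transcription factor Mef2c at 0.48 (SE 0.28), and ERK feedback genes (15 of 19, 0.15). Microglia markers were lower (12 of 14, -0.09), with Tmem119 at -0.37 (SE 0.19). The ribosomal list had adjusted p = 1.12e-13, the 4 synaptic and signalling lists 0.00270, 0.0421, 0.0276 and 0.0421, and the microglia list 0.00977. With an estimated correlation none passed: adjusted p = 0.866 with an estimated correlation for the postsynaptic list and adjusted p = 0.841 with an estimated correlation for the others. Cortex markers, which neurons of the neighbouring cortex express, moved with the synaptic lists (11 of 11 higher, 0.48, adjusted p = 0.0237, and adjusted p = 0.877 with an estimated correlation). With the choroid plexus and cortex levels as covariates, an alternative chosen after seeing the data, the ribosomal shift was -0.06 (adjusted p = 0.00153), and the synaptic and signalling shifts were 0.07 (adjusted p = 0.0609), -0.01 (adjusted p = 0.956), 0.04 (adjusted p = 0.333) and 0.07 (adjusted p = 0.164). Without saline replicate 4 these 4 shifts were 0.10 (adjusted p = 0.101), 0.02 (adjusted p = 0.840), 0.04 (adjusted p = 0.696) and 0.06 (adjusted p = 0.673), the microglia shift -0.07 (adjusted p = 0.0922), the cortex shift 0.16 (adjusted p = 0.617) and the ribosomal shift -0.07 (adjusted p = 4.64e-10). With slide as a block the shifts were -0.09 (adjusted p = 6.44e-13) for ribosomal, 0.15 (adjusted p = 0.0134) for presynaptic, 0.09 (adjusted p = 0.0849) for postsynaptic, 0.11 (adjusted p = 0.0636) for actin, 0.13 (adjusted p = 0.0778) for ERK, -0.08 (adjusted p = 0.0210) for microglia and 0.42 (adjusted p = 0.0636) for cortex genes, and the postsynaptic, actin, ERK and cortex calls ended. With 24 independent arrays they were -0.10 (adjusted p = 1.48e-13) for ribosomal, 0.18 (adjusted p = 0.000883) for presynaptic, 0.09 (adjusted p = 0.0787) for postsynaptic, 0.13 (adjusted p = 0.0134) for actin, 0.13 (adjusted p = 0.114) for ERK, -0.09 (adjusted p = 0.00270) for microglia and 0.51 (adjusted p = 0.0134) for cortex genes, and the postsynaptic and ERK calls ended. Within slides 1, 2 and 3 they were -0.23, -0.14 and 0.16 for ribosomal, 0.21, 0.47 and -0.30 for presynaptic, 0.11, 0.21 and -0.14 for postsynaptic, 0.12, 0.33 and -0.15 for actin, 0.09, 0.35 and -0.14 for ERK, -0.06, -0.07 and -0.18 for microglia and 0.35, 1.92 and -1.36 for cortex genes. On slide 3, with 2 chronic and 2 saline arrays, the ribosomal, presynaptic and cortex lists passed in the opposite direction (adjusted p = 2.47e-06, 0.00237 and 0.000738). The cortex and presynaptic shifts rest largely on chronic replicate 8. Its cortex level was -4.65, against -2.22 on the other chronic array and -2.14 and -2.01 on the saline arrays. Its presynaptic level was 0.37, against 0.88, 0.94 and 0.92, and its ribosomal level 4.19, against 4.06, 3.95 and 3.98.

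Markers of choroid plexus and of thalamus were lower in chronic than in saline rats. All 9 choroid plexus markers were lower, by a mean of -1.64 (list level -3.99 ± 1.25 against -2.35 ± 1.61, SD, n = 6 per group), with Ttr at -4.95 (SE 2.13) and Folr1 at -2.36 (SE 0.86). Of the thalamus, septum and pallidum markers 9 of 10 were lower (-0.43), with the transcription factor Zic1 at -0.84 (SE 0.37). Of the neuropeptide genes 15 of 21 were lower (-0.32). The members that moved most, Gal -1.40 (SE 0.60), Avp -1.17 (SE 0.98) and Pmch -1.01 (SE 0.87), encode peptides of hypothalamic neurons and were highest on saline replicate 4, whereas Penk, a peptide of the striatum itself, was 0.24 (SE 0.19). The adjusted p values were 2.65e-07, 1.57e-05 and 0.0206, with adjusted p = 0.841 with an estimated correlation for each. Without saline replicate 4 the shifts were -1.34 (adjusted p = 3.12e-06), -0.19 (adjusted p = 0.00416) and -0.09 (adjusted p = 0.243). Without saline replicates 4 and 5 and chronic replicate 8 they were -1.37 (adjusted p = 1.55e-05), -0.06 (adjusted p = 0.517) and 0.01 (adjusted p = 0.799), so the choroid plexus call alone held. All 3 calls held with slide as a block, at -1.62 (adjusted p = 2.61e-07), -0.40 (adjusted p = 5.21e-06) and -0.30 (adjusted p = 0.0210), and with 24 independent arrays, at -1.37 (adjusted p = 0.000283), -0.42 (adjusted p = 9.19e-06) and -0.29 (adjusted p = 0.0166). Within slides 1, 2 and 3 they were -2.15, -2.86 and 2.05 for choroid plexus, -0.14, -0.87 and -0.17 for thalamus and -0.04, -0.44 and -0.44 for neuropeptides, and on slide 3 the choroid plexus list passed in the opposite direction (adjusted p = 0.00119). There its level was -4.87 on saline replicate 8 and -1.90 on saline replicate 7, against -2.26 and -0.42 on chronic replicates 7 and 8, so the shift rests largely on saline replicate 8 and chronic replicate 8. Leaving out another unit ended further calls. Without saline replicates 2 and 5 the presynaptic, actin, cortex, postsynaptic and ERK lists had adjusted p = 0.0849, 0.0965, 0.477, 0.0837 and 0.0703. Without chronic replicate 4 the actin, cortex and postsynaptic lists had 0.0646, 0.124 and 0.0524, without chronic replicate 3 the microglia, cortex, ERK and postsynaptic lists 0.0588, 0.0513, 0.0588 and 0.0950, and without chronic replicate 7 the microglia, neuropeptide and ERK lists 0.0598, 0.0961 and 0.201. Without chronic replicates 6 and 8 the neuropeptide, ERK and postsynaptic lists had 0.0554, 0.0786 and 0.0853, and without chronic replicate 1 the ERK and postsynaptic lists 0.103 and 0.0819. The ERK or postsynaptic lists also had adjusted p of 0.0503 to 0.0559 without saline replicate 6 or 7 or acute replicate 2, 3, 5 or 7. A call could end without a smaller shift. The ERK shift was 0.17 without chronic replicate 1 and 0.16 without chronic replicates 6 and 8, against 0.15 with all units. Other shifts did fall, that of cortex to 0.20 without saline replicates 2 and 5. Of the 41 lists, 10 passed with the preset correlation. The count was 3 without saline replicate 4, 16 without saline replicate 3 and 17 without chronic replicate 4. No list passed by fry or by an exact permutation of the list means (smallest adjusted p = 0.909 and 0.877), and the other 31 lists had adjusted p of 0.0688 or more.

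No single gene passed the threshold between chronic and saline rats. By limma the smallest adjusted p was 0.693, and 585 genes had an unadjusted p under 0.05, where 1019 would be expected by chance. The count was 473 with 24 arrays as independent samples, 578 with slide as a block, 1061 with the shared letter as a random block, 2429 with array weights (smallest adjusted p = 0.0883), 1814 without saline replicate 7 and 347 without chronic replicate 3. The smallest p belonged to Vat1l, a homologue of a vesicle amine transport protein (chromosome 19, 44444792 to 44444851), with means of -2.86 ± 0.15 in chronic and -2.14 ± 0.31 in saline rats (SD, n = 6 per group). Its difference was -0.72 (SE 0.13), -0.71 with slide as a block and -0.81, -0.66 and -0.27 within slides 1, 2 and 3. Every chronic unit lay below every saline unit, but this separation is in the values by which the gene was picked and adds no evidence. The other genes had an adjusted p of 0.999. Lower were the secreted protein Ism1 -0.54 (SE 0.14), Ptger3 -0.80 (SE 0.20), the DNA repair exonuclease Exo1 -0.98 (SE 0.26) and the transcription factor Myt1 -1.23 (SE 0.35), each well above background on 2 of 8 chronic arrays, with within-slide values of -0.68, -0.42 and -0.73 for Ism1, -0.92, -0.45 and -0.97 for Ptger3, -0.93, -0.76 and -1.13 for Exo1 and -1.30, -0.55 and -1.71 for Myt1. Higher were the small RNA methyltransferase Henmt1 0.82 (SE 0.19) (chromosome 2, 204558004 to 204558063), well above background on 5 of 8 chronic and 1 of 8 saline arrays, the apoptosome scaffold Apaf1 0.42 (SE 0.11), the cysteine synthesis enzyme Cth 0.82 (SE 0.23), the Argonaute family member Piwil2 0.51 (SE 0.15) and the RNA helicase Ddx31 0.56 (SE 0.16). Within slides 1, 2 and 3 they had 0.95, 0.83 and 0.71 for Henmt1, 0.33, 0.45 and 0.13 for Apaf1, 1.28, 0.63 and -0.11 for Cth, 0.63, 0.81 and -0.25 for Piwil2 and 0.92, 0.50 and -0.18 for Ddx31, so the last 3 were lower in chronic rats on slide 3. With slide as a block the differences of these 10 genes ran from -1.20 for Myt1 to 0.82 for Henmt1. In the cell death and DNA damage list, 0 of 19 genes passed over all genes and 1, Apaf1, passed when adjusted over the list alone, while its other probe gave 0.02. In every other list of the 3 comparisons, 0 genes passed either way.

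The genes named in advance did not differ detectably between chronic and saline rats either. The immediate early genes were Fos -0.12 (SE 0.28), Fosb 0.25 (SE 0.23), Junb 0.29 (SE 0.25), Egr1 0.14 (SE 0.25), Arc 0.21 (SE 0.30) and Nr4a1 0.18 (SE 0.25). The genes of projection neurons were Drd1 0.09 (SE 0.20), Drd2 0.11 (SE 0.23), Ppp1r1b 0.26 (SE 0.25), Penk 0.24 (SE 0.19), Pdyn -0.07 (SE 0.20), Tac1 0.09 (SE 0.20) and Cartpt -0.35 (SE 0.66), and the others were Bdnf 0.44 (SE 0.43), Per1 -0.03 (SE 0.15), Per2 0.11 (SE 0.11), Fkbp5 0.26 (SE 0.14) and Th -0.13 (SE 0.23). The interval of Fkbp5 ran from -0.04 to 0.55, and that of Penk from -0.16 to 0.64. Another probe of Per1 gave 0.23. Fkbp5 had 0.20, 0.30 and 0.07 within slides 1, 2 and 3, Penk 0.21, 0.31 and 0.11 and Fos -0.45, -0.42 and 0.63, and each of the 18 genes kept its sign with slide as a block. Other alternatives did change signs: over all of them Drd1 ran from -0.16 to 0.36.

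Chronic against acute asks what 4 earlier doses changed when the last dose was the same. Ribosomal protein transcripts were lower in chronic than in acute rats: 50 of 53 were lower, by a mean of -0.12 (list level 4.04 ± 0.06 against 4.16 ± 0.09, SD, n = 6 per group), with Rpl19 at -0.25 (SE 0.09) and Rpl22 at -0.25 (SE 0.13). Presynaptic vesicle genes were higher (18 of 23, 0.14), with Syn1 0.37 (SE 0.26) and Syp 0.34 (SE 0.23). Genes of mitochondrial oxidative phosphorylation were lower in 36 of 55 (-0.02), with Uqcrq at -0.22 (SE 0.09). The chronic units are those compared with saline, so a list or gene found in both comparisons is not found independently. These 3 lists passed with the preset correlation, at adjusted p = 2.97e-18, 0.0294 and 0.0206. With an estimated correlation none passed: adjusted p = 0.841 with an estimated correlation for the ribosomal and mitochondrial lists and adjusted p = 0.877 with an estimated correlation for the presynaptic list. By an exact two-sided permutation test the ribosomal shift had p = 0.0281, and adjusted p = 0.877 over all lists and comparisons. With slide as a block the shifts were -0.14 (adjusted p = 6.12e-17), 0.14 (adjusted p = 0.0636) and -0.03 (adjusted p = 0.0391), and the presynaptic call ended. With 24 independent arrays they were -0.11 (adjusted p = 1.23e-11), 0.15 (adjusted p = 0.0338) and -0.01 (adjusted p = 0.337), and the mitochondrial call ended. In slides 1, 2 and 3 alone they were -0.06, -0.16 and -0.05 for ribosomal, 0.09, 0.39 and -0.11 for presynaptic and -0.04, 0.06 and -0.04 for mitochondrial genes. Quantile normalization, normexp background correction, the authors' values, the shared letter as a random block and array weights each put the mitochondrial shift above 0, between 2.0e-05 and 0.0043. With the choroid plexus and cortex levels as covariates the ribosomal shift was -0.10 (adjusted p = 1.24e-13), the presynaptic shift 0.08 (adjusted p = 0.0930) and the mitochondrial shift -0.02 (adjusted p = 0.122). The presynaptic list had 0.09 (adjusted p = 0.117) without chronic replicate 4, and adjusted p of 0.0503 to 0.144 without chronic replicates 2 and 5, chronic replicate 3, acute replicates 1 and 8, acute replicate 3 or acute replicates 4 and 6. The mitochondrial list had -0.02 (adjusted p = 0.0841), -0.02 (adjusted p = 0.112) and -0.01 (adjusted p = 0.374) without chronic replicate 1, acute replicate 2 or acute replicate 7. Over the 18 units the ribosomal and presynaptic lists ran in opposite directions (r = -0.746, permutation p = 0.00045, adjusted p = 0.0027 over 6 relations, and Spearman's rho = -0.674, permutation p = 0.00277). Without the 2 units farthest from the median r was -0.692, and within slides 1, 2 and 3 it was -0.652, -0.808 and -0.764. The 6 relations were chosen after list levels were seen, which the adjustment does not cover. The 3 groups were pooled, although both lists had shifts in chronic rats. Of the 41 lists, 3 passed, and 7 did without chronic replicate 4. By fry or by the exact permutation 0 lists passed (smallest adjusted p = 0.909 and 0.877), and the other 38 lists had adjusted p of 0.0869 or more. The choroid plexus list had a mean shift of -0.60 and a median of 0.01, and did not pass (adjusted p = 0.427).

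**Figure D3:**
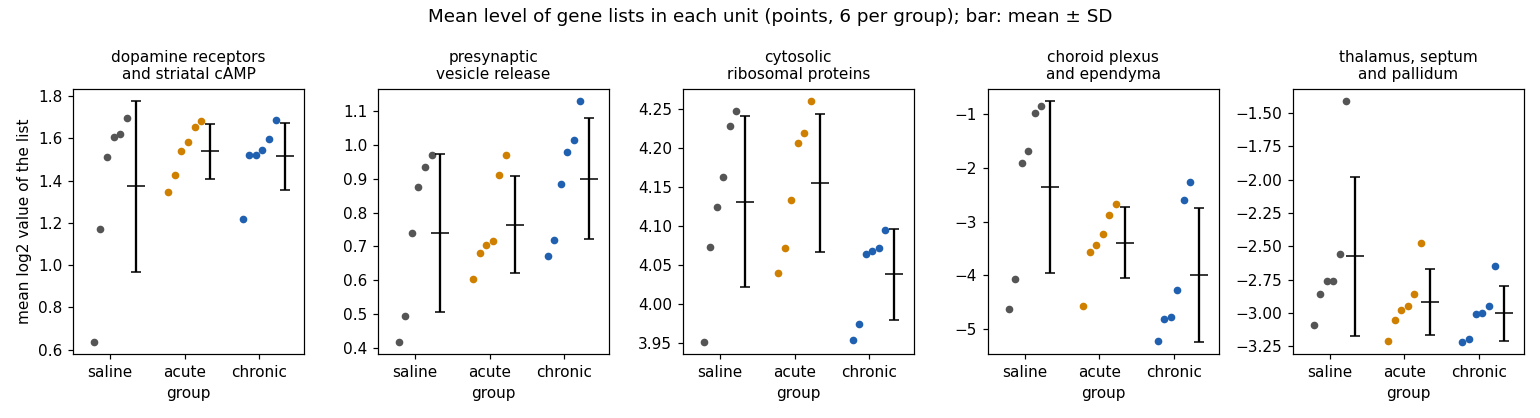
Mean log2 level of 5 gene lists (vertical axes) in each unit (points, 6 per group), with the mean and SD (bars). The ribosomal list has means of 4.13 in saline, 4.16 in acute and 4.04 in chronic rats, and the choroid plexus list spreads most.

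No single gene passed the threshold between chronic and acute rats (limma, smallest adjusted p = 0.962). At an unadjusted p under 0.05 there were 501 genes, where 1019 would be expected by chance. The count was 514 with 24 arrays as independent samples, 782 with slide as a block, 2074 with the shared letter as a random block and 4322 with array weights (smallest adjusted p = 0.189). It was 1322 without chronic replicate 1, 298 without chronic replicate 3, 299 without chronic replicate 4, 891 without acute replicate 5 and 312 without acute replicate 7. Vat1l, which had the smallest p against saline on the same chronic units, was lower in chronic than in acute rats, at -0.51 (SE 0.13), with -0.49 with slide as a block and -0.46, -0.16 and -0.45 within slides 1, 2 and 3. The G protein-coupled receptor Gpr35 (chromosome 9, 92259098 to 92259157) and the lipocalin Lcn11 were not well above background on any chronic array and were above it on 4 of 8 acute arrays. Their acute group means were at least 1.26-fold and at least 1.30-fold higher, bounds that leave out the spread between units. Hcst was lower at -0.86 (SE 0.24), and N4bp1, a regulator of ubiquitin ligases, at -0.35 (SE 0.10), while another probe of N4bp1 gave 0.18. Hcst had -0.87, -0.91 and -0.73 and N4bp1 -0.41, -0.44 and -0.20 within slides 1, 2 and 3. Higher were Vps33a, a subunit of the complexes that tether endosomes and lysosomes (chromosome 12, 34188686 to 34188745), at 0.49 (SE 0.12), Ddx31 0.58 (SE 0.16), Dip2a 0.37 (SE 0.11), the interferon receptor subunit Ifnar1 0.28 (SE 0.09) and Cacna1a, the pore of P/Q-type calcium channels, at 0.41 (SE 0.13), whose other probe gave 0.09. Their within-slide values were 0.58, 0.49 and 0.35 for Vps33a, 0.70, 0.20 and 0.42 for Ddx31, 0.32, 0.32 and 0.29 for Dip2a, 0.22, 0.17 and 0.38 for Ifnar1 and 0.45, 0.40 and 0.24 for Cacna1a. A slide block gave 0.51, 0.56, 0.39, 0.31 and 0.46, Hcst -0.87 and N4bp1 -0.39. Each of these genes had an adjusted p of 0.962. Among the genes named in advance, the immediate early genes were Fos 0.04 (SE 0.28), Fosb 0.16 (SE 0.23), Junb 0.45 (SE 0.25), Egr1 0.21 (SE 0.25), Arc 0.04 (SE 0.30) and Nr4a1 -0.01 (SE 0.25). The genes of projection neurons were Drd1 -0.20 (SE 0.20), Drd2 -0.14 (SE 0.23), Ppp1r1b 0.14 (SE 0.25), Penk 0.03 (SE 0.19), Pdyn -0.40 (SE 0.20), Tac1 -0.10 (SE 0.20) and Cartpt -0.61 (SE 0.66), and the others were Bdnf 0.39 (SE 0.43), Per1 -0.09 (SE 0.15), Per2 0.05 (SE 0.11), Fkbp5 0.08 (SE 0.14) and Th 0.13 (SE 0.23). The interval of Pdyn, the dynorphin precursor of the direct pathway, ran from -0.83 to 0.03, with -0.13, -0.96 and -0.14 within slides, and that of Junb from -0.08 to 0.98, with 0.70, 0.00 and 0.78. Nr4a1 changed sign to 0.11 with slide as a block. Another probe of Drd1 gave 0.08, and another of Per1 gave 0.28.

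Across all 3 groups, no gene passed limma's F test (smallest adjusted p = 0.996), with 351 genes at an unadjusted p under 0.05, 295 with 24 arrays as independent samples and 470 with slide as a block. Effects of the acute and chronic treatment, each against saline, were correlated across the 20388 genes (r = 0.562), and 61.8% of genes had the same sign. Both effects share the saline group, and genes are not independent replicates. In 100 simulated sets of unchanged groups that share controls in the same way, r was 0.499 on average (0.463 to 0.533), and the covariance of 0.0203 differed from the simulated 0.0202 by 5.64e-05. These sets kept the spread of each gene alone and not how genes vary together, so their range is too narrow to judge the real r. Of 100 regroupings of the same units, the real groups included, 33 had r as high, with a highest of 0.768. With the 6 saline units split so that each comparison had 3 of its own, r averaged -0.057 over 20 splits, with a range from -0.277 to 0.185. The correlation was 0.433 with slide as a block, 0.456 with 24 arrays, and 0.575, 0.434 and 0.562 within slides 1, 2 and 3. It ran from 0.449 to 0.674 when 1 unit was left out.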

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

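The search for samples standing apart was fixed before values were seen, and the tests of explanations and of other splits of the samples were chosen after the results they measure were seen. In each group, the highest or lowest unit was picked out when its gap to the nearest other unit, as a share of the group's range, exceeded Dixon's 95% critical value for 6 samples. Chance picks out about 1 in 20 groups, 12.75 of the 255 groups tested here, and 21 stood apart, 7 of them by saline replicate 4. Values are log2 differences from the mean of the other 5 units of the group. Saline replicate 4 was high for the neuropeptide (1.37), thalamus, septum and pallidum (1.40), oligodendrocyte (0.62) and oligodendrocyte precursor (0.48) lists and low for the postsynaptic density list (-0.46), Fosb (-1.17) and Nr4a1 (-1.11). Chronic replicate 4 was low for the pan-striatal (-0.57), indirect-pathway (-0.49) and dopamine and cAMP (-0.36) lists, Drd1 (-0.75) and Drd2 (-0.77). Saline replicate 3 was low for the endothelium (-0.27) and histone and DNA methylation (-0.16) lists, and saline replicate 6 was high for GABA signalling (0.21) and low for Vps33a (-0.55). Among acute units, the mean of replicates 4 and 6 was high for Exo1 (1.04) and Ptger3 (1.02), replicate 7 was high for Myt1 (1.19) and replicate 3 was low for Bdnf (-1.20). Chronic replicate 3 was high for the interferon response list (0.51).

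Saline replicate 4 combined low striatal with high hypothalamic transcripts. By the percent of spots well above background it did not stand apart: 63.7%, within the 50.7% to 71.3% of the other arrays. One measure inside the range of the others cannot exclude array or RNA quality, and no other measure was tested. Hypothalamic markers were listed after the array was seen to stand apart, and 6 of them had already been seen in earlier results, so their test is not independent of the pattern. They were higher on it in 10 of 11 measured genes, with a median difference of 1.46, above the upper bound of 0.29 from 10000 random lists of like level. The most raised were Gal (4.15), Arhgap36 (3.48), Trh (3.19) and Magel2 (2.86), and 3 of the 21 listed genes are also in the neuropeptide list. Hypothalamic tissue in the piece is a candidate explanation that these genes cannot settle, and since the array is a single sample of its group, no biological explanation was tested.

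Choroid plexus levels ran from -4.87 to -0.03 over saline, -4.72 to -2.15 over acute and -5.22 to -0.42 over chronic arrays, and cortex levels from -4.83 to -1.58, -3.18 to -2.02 and -4.65 to -1.58, with the lowest cortex levels on saline replicates 4 and 5 and chronic replicate 8. The choroid plexus level had a correlation of -0.0862 (bootstrap interval -0.509 to 0.344) with the percent of spots well above background. This argues against a correlation of 0.7 or stronger in either direction, a bound set after results were seen. A weaker relation and other measures of quality are not excluded. The cortex level was not tested in this way. The second principal component, which followed the cortex list (r = 0.658), had r = -0.424 with that percent. Choroid plexus markers moved together, with a mean pairwise correlation of 0.443 against a 95th percentile of 0.197 in random lists of like spread, and cortex markers had 0.697 against 0.150. Neighbouring tissue in the dissected piece may explain this. Slide (13.8% of the variance, interval 1.86 to 53.2) and treatment group (13.2%, interval 0.693 to 57.2) cannot be told apart from other sources, because the intervals reach past 50%.

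Ribosomal protein transcripts were lower in chronic than in acute rats. Splits of these units called the list in 62 of 100 cases. Genes that vary together could therefore account for its passing camera with a preset correlation, but not as readily for the size of the shift. The shift was as large in 2 and camera's p as small in 3 of the 100, the real split included. Against saline 61 splits called the list, 10 had a shift as large and 2 a p as small. Chance among the lists tested stays open as well, with an adjusted exact permutation p of 0.877. Neighbouring tissue cannot be told apart: with choroid plexus and cortex levels as covariates the shift was -0.10 (SE 0.04), against -0.12 (SE 0.05) without. A response to repeated MDPV stays open, as untested beyond these values.

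Splits of the same samples, 100 for each result, were compared with the real groups. With a real count of 0 genes past the threshold in each comparison and in the F test, all 100 splits must give as many, so these say nothing about chance; the highest other counts were 1 in each comparison and 439 in the F test. At an unadjusted p under 0.01 the real counts of 41, 63 and 50 genes were reached in 100, 88 and 60 splits, with highest other counts of 1047, 1599 and 1165. The real counts of 11, 10 and 3 lists past the threshold were reached in 24, 36 and 86 splits, with highest other counts of 17, 20 and 13. The correlation of acute and chronic effects, 0.562, was reached in 33 regroupings, with a highest of 0.768. Chance is not excluded for these counts of genes at p under 0.01, of lists, or for the correlation. Splits that call many times the real number of genes point to a structure of the samples that the groups do not follow.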

How the results depend on the processing

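Values with the covariates, with the arrays left out as arrays and by exact permutation come from alternatives chosen after seeing the data, and the others were fixed beforehand. The spread used to judge the correlation of effects, and the rule that a list reverses when its mean shift changes sign, were changed after results were seen. The cause was not tested for any change below except where fewer arrays show it. No gene passed in any comparison or in the F test under any alternative run. The differences of the named genes moved by at most 1 SE in 1440, 1461 and 1489 cases for acute against saline, chronic against saline and chronic against acute. They moved further in 140, 115 and 97 and, for the genes of smallest p, reversed in 4, 7 and 1. Within the first 2 kinds, genes named whatever their values changed sign in 89, 75 and 63 cases. List calls held in 313, 299 and 92 cases, were no longer past the threshold in 149, 127 and 33 and reversed in 20, 10 and 7. These tallies, of genes and of lists, overstate stability, because some alternatives leave the differences the same by construction. They are a unit left out of the group not compared, only the compared groups, robust and trended moderation, and the other list tests. Leaving out saline replicate 4 as a unit and as an array is the same fit, counted under both names. The number of lists past the threshold, 11, 10 and 3, was 0 in each comparison with an estimated correlation, by fry and by exact permutation. In the order of the 3 comparisons, leaving out 1 unit gave 3 to 16, 3 to 17 and 2 to 7 lists. A count under an alternative can include lists that did not pass in the main test, which are not named. The 1 list counted for acute against saline without saline replicates 4 and 5 and chronic replicate 8 is such a list. For acute against saline the number was 5 with normexp, 6 with the letter as a random block, with or without slide as a block, 1 with the arrays of digit 1 alone, 7 within slide 1, 3 within slide 3, 3 with array weights, 3 with the covariates, 2 with the covariates over 24 arrays, 3 without saline replicate 4 and 1 without saline replicates 4 and 5 and chronic replicate 8. For chronic against saline it was 19 with no filter on dim probes, 6 with slide as a block, 5 within slide 1, 6 with array weights, 6 with the covariates on either 18 units or 24 arrays, 3 without saline replicate 4 and 5 without these 3 arrays. For chronic against acute it was 9 with no filter, 8 with the arrays of digit 0 alone, 10, 8 and 10 within slides 1, 2 and 3, and 1 with the covariates. The mitochondrial shift in chronic against acute turned to 0.0017 with quantile normalization, 0.00089 with normexp, 0.0043 with the authors' values, 0.0012 with the letter as a random block, 2.0e-05 with array weights and 0.065 within slide 2. Among acute against saline shifts, slide 1 turned Akap5 to -0.21, the ERK list to -0.020, pan-striatal to -0.020, oligodendrocytes to 0.14 and thalamus to 0.048. Slide 2 turned Fam107b to 0.14. Slide 3 turned the dopamine list to -0.075, pan-striatal to -0.082, direct-pathway to -0.029, indirect-pathway to -0.082, oligodendrocytes to 0.023 and choroid plexus to 0.60. Array weights turned oligodendrocytes to 0.0071, the covariates to 0.014, and the covariates over 24 arrays to 0.0038. Without saline replicates 4 and 5 and chronic replicate 8 the ERK list had -0.015, dopamine -0.035, channels -0.0044, pan-striatal -0.046, indirect-pathway -0.00021, oligodendrocytes 0.018 and thalamus 0.0095. Tmem51 turned to -0.053 when a probe had to be above background on every array of a group, where another probe stood for the gene, and Fam107b to 0.96 with outlier spots kept. Among chronic against saline shifts, slide 3 turned choroid plexus to 2.05, cortex to -1.36, ribosomal genes to 0.16, presynaptic to -0.30, postsynaptic to -0.14, actin to -0.15 and the ERK list to -0.14. It also turned Cth to -0.11, Piwil2 to -0.25, Ddx31 to -0.18, Wipf2 to -0.08, Cd7 to -0.15, Stx7 to -0.092 and Dynlrb2 to 0.84. The postsynaptic list turned to -0.012 with the covariates and to -0.00072 without the 3 arrays, and the neuropeptide list to 0.013 without them. Among chronic against acute shifts, slide 3 turned the presynaptic list to -0.11, and outlier spots kept turned Ppp6c to -1.33. The correlation of acute and chronic effects was 0.258 with the arrays of digit 1 alone and -0.057 with the saline units split between the comparisons, whose construction removes the shared controls. No paired analysis was possible because no label pairs a rat of one group with a rat of another. Results are not given for the F test with only the compared groups or for lists under trended moderation. Nor are they given for the choroid plexus and cortex lists under covariates made from them. These 2 lists were still tested there, so the counts of lists past the threshold with the covariates can include them. Such a test is circular. Signal over background limits the dimmest genes: Gpr35 and Lcn11 were not well above background on any chronic array. Only bounds between group means of at least 1.26-fold and at least 1.30-fold could be given, without the spread between units. Among the markers, Slc17a7, Avp, Folr1 and Pmch were well above background on 21, 21, 19 and 17 of the 24 arrays. Their lowest values, and differences that rest on them, may therefore reflect background.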

Other observations

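The camera tests were fixed beforehand, and the exact permutations and the relations between lists were chosen after seeing the data. Of the 41 lists, 22 passed in none of the 3 comparisons by camera with a preset correlation. Mean log2 shifts for acute against saline, chronic against saline and chronic against acute (6 units per group) were 0.07, 0.15 and 0.09 for immediate early genes, -0.03, -0.06 and -0.03 for opioid and endocannabinoid signalling, -0.03, 0.01 and 0.04 for the synthesis and breakdown of monoamines, 0.02, 0.06 and 0.05 for receptors for serotonin, noradrenaline, acetylcholine and trace amines and 0.02, 0.05 and 0.03 for glutamate receptors. They were 0.00, 0.03 and 0.02 for GABA signalling, -0.06, -0.09 and -0.04 for neurotrophins and growth factors, 0.05, 0.08 and 0.03 for circadian clock, -0.07, 0.01 and 0.09 for glucocorticoid-induced genes and -0.03, 0.04 and 0.08 for heat shock and cytosolic chaperones. They were 0.00, 0.05 and 0.05 for endoplasmic reticulum stress and amino acid response, -0.06, 0.00 and 0.06 for oxidative stress and NRF2 targets, 0.01, 0.04 and 0.03 for histone modification and DNA methylation, 0.01, -0.02 and -0.03 for inflammation and -0.01, 0.08 and 0.09 for cell death and DNA damage. Among marker lists they were 0.02, -0.14 and -0.16 for cholinergic interneurons, -0.02, -0.04 and -0.02 for GABA interneurons, 0.20, -0.18 and -0.38 for ventromedial striatum and -0.04, -0.04 and 0.00 for astrocytes. They were -0.10, -0.11 and 0.00 for oligodendrocyte precursors, -0.04, 0.02 and 0.05 for endothelium and mural cells and -0.14, -0.10 and 0.04 for meninges and fibroblasts. By exact permutation the heat shock list had p = 0.00866 in chronic against acute, with 16 of 21 genes higher, Dnajb1 0.18 (SE 0.10) and Hsph1 0.16 (SE 0.09), and 0.04, 0.06 and 0.11 within slides 1, 2 and 3. The circadian list had exact permutation p = 0.0303 in chronic against saline, with Clock at 0.66 (SE 0.22). Both had an adjusted exact permutation p of 0.877.

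The mean, the median and camera's direction differed in sign in lists that did not pass. In acute against saline these were GABA signalling, endoplasmic reticulum stress, histone modification, inflammation, cell death, cholinergic interneurons and endothelium. In chronic against saline it was the glucocorticoid list. In chronic against acute these were the opioid, serotonin, glutamate, GABA signalling, channel, circadian, choroid plexus and meninges lists.

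Of the 6 relations tested between list levels over 18 units, the other 4 did not pass. Choroid plexus and cortex had r = -0.405 (permutation p = 0.0977, adjusted p = 0.195), with rho = -0.298 (permutation p = 0.231), r = -0.443 without the 2 units farthest from the median, and 0.254, -0.913 and -0.731 within slides 1, 2 and 3. Choroid plexus and ribosomal genes had r = 0.359 (permutation p = 0.144, adjusted p = 0.216) and rho = 0.265 (permutation p = 0.284), r = 0.179 without the 2 farthest units, and 0.548, 0.476 and 0.387 within slides. Cortex and immediate early genes had r = 0.254 (permutation p = 0.297, adjusted p = 0.297) and rho = -0.249 (permutation p = 0.317), r = -0.349 without the 2 farthest units, and -0.264, 0.489 and -0.396 within slides. Oligodendrocytes and pan-striatal neurons had r = -0.320 (permutation p = 0.191, adjusted p = 0.230) and rho = -0.245 (permutation p = 0.327), r = 0.170 without the 2 farthest units, and 0.194, -0.628 and 0.0168 within slides. The adjusted p of rho was 0.327 for each of these 4.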
